A study of Homo sapiens with 43 samples.

How the data were processed

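Per the labels' protocols, G401 cells were engineered to express GFP or SMARCB1 under doxycycline and given control or NSD1 guide RNAs, and other G401 cells stably expressed a control or an NSD1 hairpin and received DMSO or GSK126. RNA was isolated with Trizol and a column kit, and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.3 and the genome build was GRCh37; the aligner and the annotation release are not given in the sources used here. The notes name no counting tool, though the name of the deposited table of expected counts holds RSEM; for the hairpin table none is given. For the guide RNA experiment the authors deposited expected counts per gene, not scaled between libraries: 27665 values were not whole, and 27038 of 57912 genes had no count in any library. For the hairpin experiment the deposited values are whole counts per gene for 32754 genes, 6668 of them without a count in any library. The 92 spike-in entries in the table of expected counts held 0 counts. Genes carry Ensembl identifiers; symbols were taken from the table of expected counts for the 32041 identifiers found in both tables, and 713 of the hairpin table had none. NSD1, SMARCB1 and EZH2 were found by symbol. The table of whole counts has no counts for the mitochondrial genome, so the mitochondrial share was measured in the guide RNA experiment alone.

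Depth ran from 56.9 to 127.3 M expected counts per library in the guide RNA experiment and from 29.8 to 63.8 M counts in the hairpin experiment. A count of 0 allows 3 counts, which is 0.0234 to 0.0531 CPM and 0.0449 to 0.103 CPM per library. Samples were grouped by their titles into 4 groups of 4 libraries and into groups of 7, 7, 8 and 5. Each experiment was analysed alone.

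Expected counts were rounded, genes were kept by edgeR's filterByExpr by group with a minimum count of 10, libraries were scaled by TMM, and each comparison was tested in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test in a model of 4 group means per experiment. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the calls that changed at least 2-fold (a log2 fold change of 1) were counted too. This left 17367 and 15454 genes. The comparisons were SMARCB1 against GFP with each guide, the NSD1 guide against the control guide with GFP and with SMARCB1, GSK126 against DMSO with each hairpin, the NSD1 hairpin against the control hairpin in DMSO and in GSK126, and the difference of effects in each experiment. The median SE of a log2 fold change was 0.071 in the guide RNA comparisons of 2 groups, and 0.126 to 0.142 in those of the hairpin experiment; for the differences it was 0.1 and 0.189. The comparisons, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined.

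Genes were named by a fixed rule: NSD1, SMARCB1 and EZH2; per comparison of 2 groups the 8 steepest rises and 8 steepest falls (ranked with a prior count of 2) among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, clone, antisense, pseudogene and non-coding locus names left out; per difference the 8 smallest p in each direction; and up to 4 members of each list with the smallest adjusted p. At most 1 gene per comparison was left out by name. Folds are not printed where 1 group had a mean of under 6 counts per library; for such genes the CPM are given, and this bound was chosen only after the data were seen.

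The 30 lists were PRC2 subunits, PRC1 subunits, SWI/SNF subunits, H3K36 methyltransferases and demethylases, HOX genes, developmental transcription factors under Polycomb, cell-cycle inhibitors, proliferation genes, p53 targets, ribosome biogenesis genes, hedgehog genes, neuronal genes, contractile genes, extracellular matrix genes, YAP targets, TGF-beta response genes, antigen presentation genes, interferon-stimulated genes, inflammatory NF-kB targets, MAPK feedback and immediate-early genes, cholesterol synthesis genes, unfolded protein and stress response genes, hypoxia and glycolysis genes, kidney development genes, imprinted genes, germline genes silenced by DNA methylation, and markers of immune, endothelial, epithelial and red cells. Lists with under 3 measured members were not tested, which left out germline and red cell genes in both experiments and endothelial markers in the hairpin experiment. Each list was tested by camera with a preset correlation of 0.01 and with an estimated correlation, and by fry (limma 3.58.1), with p adjusted over the lists of a comparison. fry tests whether a set moves one way on balance and does not compare it with other genes. Members called are given over all genes and adjusted over the list alone.

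Sets raised at least 2-fold were chosen in some libraries and measured in others (odd against even title numbers for GSK126, R2 against R3 for SMARCB1), and sets from each experiment were tested in the other. Overlaps were compared with the product of the list sizes over the genes tested in both, with Fisher's exact test. Shares of counts per library were compared by two-sided exact permutation tests.

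Whether equal title numbers pair libraries was checked before the fits were compared, by the correlation over genes of their deviations from group means, with pairing taken to hold if every pair passed 0.1. In the hairpin experiment it did within each hairpin: 0.192 to 0.655 in shCTRL (7 of 7 pairs) and 0.501 to 0.701 in shNSD1 (5 of 5). Libraries of other numbers but the same hairpin and run gave 0.0876 to 0.58 (10 of 11 over 0.1). Same-numbered pairs within a hairpin all share a run, so pairing by number is not told apart from the run. Between hairpins equal numbers gave -0.377 to 0.529 (19 of 24 over 0.1), and libraries of one run 0.116 to 0.627 (44 of 44), and the first principal component (37.4% of the variance) followed the run, which explained 90.7% of it. Pair-blocked and run-blocked values therefore stand beside those results. No library was a copy of another of its group (24 pairs in the guide RNA and 80 in the hairpin experiment). Libraries of different groups were not compared in this way.

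The procedure was tested on simulated data with the same group sizes. For changes of 1.5, 2 and 4-fold, edgeR recovered 72.7, 86.4 and 100% for SMARCB1 with the control guide, 69.8, 84.8 and 98.4% with the NSD1 guide, 72.7, 86.4 and 98.4% for the NSD1 guide in GFP cells and 69.8, 83.3 and 98.4% in SMARCB1 cells. It recovered 54.5, 80.6 and 90.6% for GSK126 in shCTRL, 44.8, 68.7 and 92.2% in shNSD1, 51.5, 86.6 and 90.6% for the NSD1 hairpin in DMSO and 47.8, 67.2 and 95.3% in GSK126. For the difference of effects, with changes placed in either arm, it recovered 62.1 to 63.5, 77.3 and 93.8 to 95.3% in the guide RNA design and 28.8 to 29.9, 61.2 to 70.1 and 76.6 to 85.9% in the hairpin design. Wrong calls were 2.17 to 7.43% of all calls. These libraries were simulated without run, pair or title series effects. Neither the recovery nor the share of wrong calls need therefore hold for the real libraries. Of 240 lists without simulated change camera called 0 at an unadjusted p under 0.05 with either correlation. It called 12 of 12 raised lists at the preset correlation, the only one counted for them. Simulated genes were drawn independently, so these lists cannot show how often preset calls are wrong where genes of a list are correlated. A held-out set with a true difference of -1 was measured at -0.98 and -1, and one with 0 at -0.01 and 0.0016.

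Alternatives were other scaling factors, library totals, no filter, a stricter filter of 1 CPM, DESeq2 1.42.0, limma-voom, only the compared groups in the fit, title-number and run blocks, single title series, each library left out, sets without fold minimum, and estimated correlations. Added after the data were seen were pair blocks within each hairpin, runs 1 to 3 alone, leaving out a pair of doubted libraries, and a list of motile cilia genes. Other splits of the libraries were counted for each comparison, all 35 for 4 against 4 and a seeded draw of 100 for the larger ones. Gene-level coordinates were not used, and no sample was left out.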

Results

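RNA was sequenced from G401 cells, a malignant rhabdoid tumour line that lacks the chromatin remodelling subunit SMARCB1, in 2 experiments on NSD1, an enzyme that methylates lysine 36 of histone H3. In the guide RNA experiment, cells carrying doxycycline-driven GFP or SMARCB1 also received a control guide (sgC) or an NSD1 guide (sgN), and RNA was taken 24 h after 1 ug/mL doxycycline. Its 16 libraries form 4 groups of 4, with 56.9 to 127.3 M expected counts per library. In the short hairpin experiment, cells with a control hairpin (shCTRL) or an NSD1 hairpin (shNSD1) were kept in DMSO or in 1 uM GSK126, an inhibitor of the Polycomb methyltransferase EZH2, for 72 h. Its 27 libraries are 7 shCTRL DMSO, 7 shCTRL GSK126, 8 shNSD1 DMSO and 5 shNSD1 GSK126, with 29.8 to 63.8 M counts each. Values written after ± are standard errors unless SD is stated, computed as the absolute log2 fold change over the square root of its F statistic. The n is 4 libraries per group in the guide RNA experiment and the group sizes above in the hairpin experiment. The labels do not say that libraries of a group are separate cultures, so every p measures only the spread between these libraries.

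The 3 manipulated genes come first. SMARCB1 was at 0 counts in all 4 GFP sgC libraries and at a mean of 3925 CPM (counts per M counts of the library, scaled by TMM; SD 323, n = 4) in SMARCB1 sgC libraries, at least 95600-fold higher against a floor of 3 counts per library. In SMARCB1 sgN libraries it had a mean of 3510 CPM (SD 173, n = 4). Of the 4 GFP sgN libraries, 2 had no SMARCB1 count, 1 had 0.0095 CPM and replicate 2_R2 had 22.05 CPM. The NSD1 guide left NSD1 mRNA at 150.3 CPM (SD 7.13) in GFP cells, against 140.1 CPM (SD 8.02) with the control guide (log2 fold change 0.10 ± 0.09, edgeR adjusted p = 0.55). In SMARCB1 cells NSD1 mRNA was 138.1 CPM (SD 18.9) against 130.6 CPM (SD 17) (0.08 ± 0.09, edgeR adjusted p = 0.668), and RNA levels do not report whether a guide has cut its gene. The NSD1 hairpin lowered NSD1 mRNA to 138 CPM (SD 15, n = 8) from 198.2 CPM (SD 23.5, n = 7) in DMSO, a log2 fold change of -0.52 ± 0.09 (edgeR adjusted p = 0.000404). In GSK126 it lowered NSD1 mRNA to 126.8 CPM (SD 23, n = 5) from 191.8 CPM (SD 14.8, n = 7), a log2 fold change of -0.60 ± 0.10 (edgeR adjusted p = 0.00057). SMARCB1 was at 0 counts in all 27 hairpin libraries, where 3 counts would be 0.0449 to 0.103 CPM; floors cover counting error only. EZH2, the target of GSK126, did not pass the test with GSK126 (-0.11 ± 0.14 in shCTRL, 0.10 ± 0.15 in shNSD1) and rose with SMARCB1 by 0.43 ± 0.03 in sgC cells (edgeR adjusted p = 6.71e-10).

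**Figure D1:**
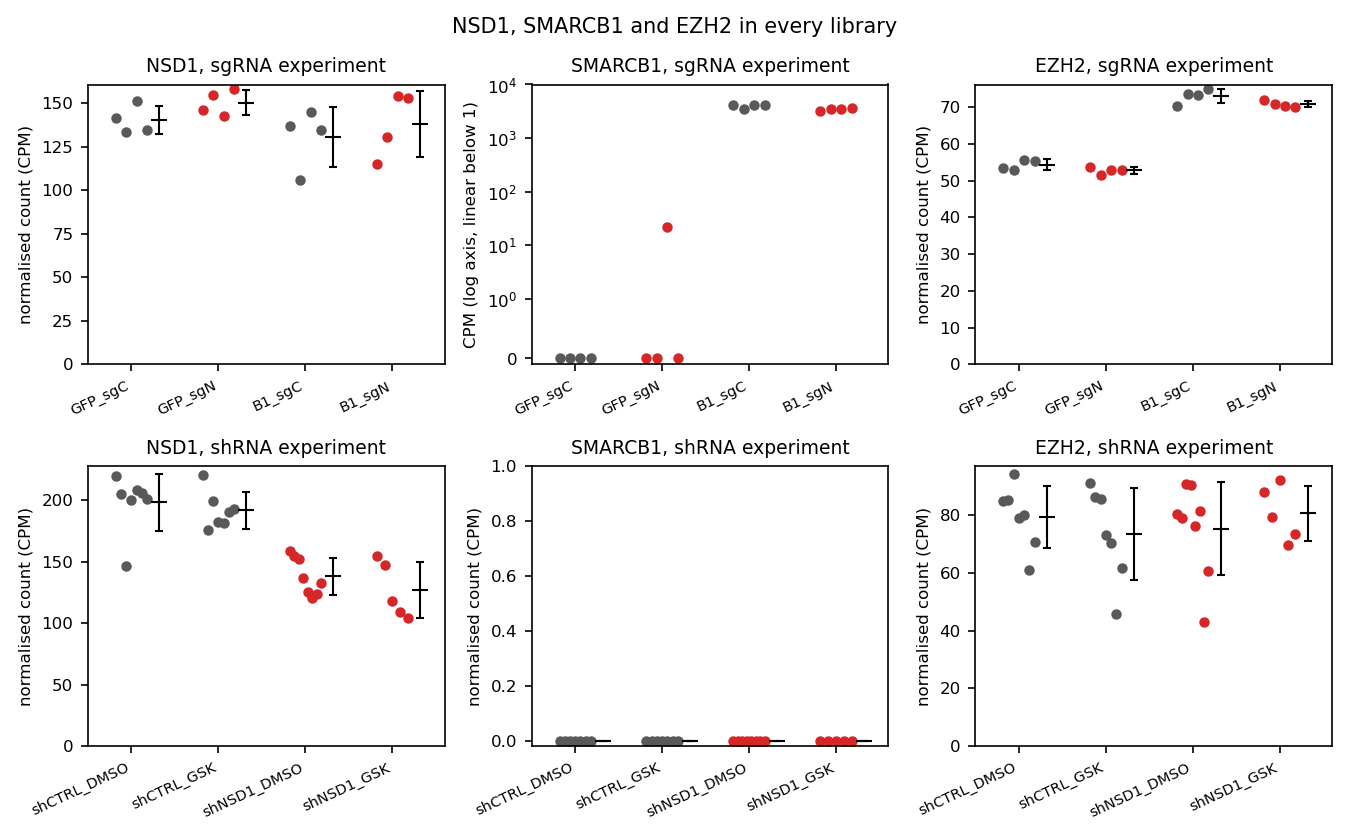
CPM (counts scaled to library size) of NSD1, SMARCB1 and EZH2 in every library (points), by group, with the group mean and SD (line and bar) except for SMARCB1 in the guide RNA experiment, whose axis is logarithmic above 1 and linear below. NSD1 mRNA had a lower mean with the NSD1 hairpin (138 against 198.2 CPM in DMSO), though shCTRL DMSO 3 (146.8 CPM) lay among its libraries. Between guides it overlapped.

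The first comparison asks what SMARCB1 does to these cells when the control guide is present. ZSWIM6 (8.44 ± 0.14), the carboxypeptidase CPA4 (7.24 ± 0.11) and the synaptic adhesion gene NLGN1 (7.30 ± 0.19) were among the steepest rises in log2 fold change. The proprotein convertase gene PCSK6 rose from 0.061 to 15.1 CPM and the melanosome transport gene MLPH from 0.0359 to 8.21 CPM, with too few counts in GFP cells for a fold. Every SMARCB1 library lay above every GFP library for each of them. RFPL4B (-9.24 ± 0.25), the microfibril gene FBN2 (-9.06 ± 0.26) and the kidney growth factor BMP7 (-8.66 ± 0.23) were among the steepest falls. GPX3, a secreted glutathione peroxidase gene, fell from 24.5 to 0.029 CPM. MGST1 had a mean of 50.1 CPM in GFP cells and 0.0189 CPM in SMARCB1 cells, too few counts for a fold. DIAPH2, a formin, had no count in GFP sgC cells and was at least 340-fold higher with SMARCB1 against the floor of 3 counts per library. In all, 5717 genes rose and 5553 fell of 17367 tested by edgeR at an adjusted p under 0.05, of which 1157 and 1712 changed at least 2-fold.

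Among the gene lists, 21 of 34 measured HOX genes, which set position along the body axis, rose with SMARCB1 and 8 fell, including HOXD8 (2.94 ± 0.16), HOXD9 (2.65 ± 0.10), HOXB9 (1.55 ± 0.04) and HOXB13 (-2.11 ± 0.08). The camera set test called the HOX list higher (adjusted p = 0.0172; adjusted p = 0.254 with an estimated correlation). Of 45 proliferation genes, 31 rose and 3 fell, with CCNE2 at 1.27 ± 0.08, PLK1 at 0.56 ± 0.03 and E2F2 at -0.67 ± 0.05 (camera adjusted p = 0.0172; adjusted p = 0.254 with an estimated correlation). Of 25 extracellular matrix genes, 14 rose and 6 fell, with the laminin LAMB1 at 5.56 ± 0.07, SPARC at 1.98 ± 0.05 and the laminin LAMA4 at -5.56 ± 0.09 (0.0172; adjusted p = 0.254 with an estimated correlation). Of 17 hypoxia and glycolysis genes, 12 rose and 2 fell, with PDK1 at 1.61 ± 0.08 and the glucose transporter SLC2A1 at -2.38 ± 0.09 (0.0471; adjusted p = 0.279 with an estimated correlation).

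In the other direction, 14 of 23 p53 target genes fell with SMARCB1 and 4 rose, with FDXR at -1.28 ± 0.07 and the repair gene DDB2 at -1.13 ± 0.05 (camera adjusted p = 0.0228; adjusted p = 0.607 with an estimated correlation). Of 15 antigen presentation genes, 9 fell and 5 rose, with TAP1 at -1.41 ± 0.05 and CD74 at -1.29 ± 0.04 (0.0471; adjusted p = 0.254 with an estimated correlation). Of 7 epithelial markers, 5 fell and 1 rose, with KRT18 at -1.28 ± 0.05 and KRT8 at -1.09 ± 0.04 (0.0407; adjusted p = 0.254 with an estimated correlation). For each of these lists the counts adjusted over the list alone equalled those over all genes.

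The camera test called no other list, though most had members that changed both ways. Developmental transcription factors under Polycomb gave 16 up and 9 down of 27, with GATA6 at 2.75 ± 0.06, FOXC2 at 1.97 ± 0.07 and ALX4 at -1.06 ± 0.04. PRC2 subunits gave 6 up and 4 down of 12, with JARID2 at 0.73 ± 0.06 and EED at 0.52 ± 0.05. PRC1 subunits gave 8 and 6 of 18, SWI/SNF subunits 14 and 7 of 26, and H3K36 methyltransferases and demethylases 3 and 4 of 11, with SMYD2 at 1.59 ± 0.04. The hedgehog target GLI1 (-2.62 ± 0.08) fell, while 4 of 7 hedgehog genes rose. MAPK feedback and immediate-early genes gave 7 up and 9 down of 23, with SPRY2 at 3.39 ± 0.09, JUN at 2.11 ± 0.08 and FOS at -2.48 ± 0.09. Cholesterol synthesis genes gave 5 up and 11 down of 21, with STARD4 at -1.93 ± 0.05. Contractile genes gave 8 up and 3 down of 15, with SYNPO2 at 0.0359 CPM with GFP and 2.63 CPM with SMARCB1, and kidney development genes 3 up and 3 down of 7, with PAX2 at -3.88 ± 0.18. Imprinted genes gave 9 up and 5 down of 14, with PLAGL1 at 2.24 ± 0.06 and DLK1 at -2.72 ± 0.16. Up and down counts were 6 and 4 of 11 cell-cycle inhibitors, 15 and 5 of 27 ribosome biogenesis genes, 9 and 6 of 16 YAP targets, 4 and 7 of 15 TGF-beta response genes, and 4 and 10 of 17 interferon-stimulated genes. They were 2 and 9 of 13 inflammatory NF-kB targets, 11 and 5 of 21 unfolded protein and stress response genes, 5 and 3 of 8 neuronal genes, 1 and 3 of 4 immune cell markers, and 2 and 1 of 3 endothelial markers. The share of counts from the mitochondrial genome was 7.72% with SMARCB1 and 8.82% with GFP (n = 4 each; two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give; adjusted p = 0.229 over 48 tests).

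SMARCB1 was then compared with GFP in cells with the NSD1 guide. ZSWIM6 (8.34 ± 0.14) and CPA4 (7.50 ± 0.12) again rose, and BMP7 (-8.71 ± 0.24), GPX3 (-8.43 ± 0.21) and the copper carrier CP (-7.43 ± 0.20) fell, with no overlap between the libraries of the groups. HOX genes gave 25 up and 3 down of 34, with HOXB9 at 1.96 ± 0.04 (camera adjusted p = 4.86e-05; adjusted p = 0.149 with an estimated correlation). Extracellular matrix genes gave 17 up and 5 down of 25, with LAMB1 at 5.73 ± 0.07 and SPARC at 2.67 ± 0.05 (4.86e-05; adjusted p = 0.149 with an estimated correlation). Developmental transcription factors gave 16 up and 8 down of 27, with FOXC2 at 2.44 ± 0.07 and DLX1 at 2.04 ± 0.05 (0.0194; adjusted p = 0.228 with an estimated correlation). YAP targets gave 10 up and 5 down of 16, with the receptor AXL at 2.07 ± 0.05 (0.0258; adjusted p = 0.36 with an estimated correlation). Of 4 immune cell markers 3 fell, with CSF1R at -2.93 ± 0.12 (0.024; adjusted p = 0.149 with an estimated correlation). For these lists too, the counts adjusted over the list alone were the same. By edgeR 5606 genes rose and 5266 fell of 17367, 1366 and 1499 of them at least 2-fold. Of the genes called in either guide background, 4853 rose in both and 4622 fell in both, where independent lists would share 1845 and 1684. The mitochondrial share was 7.99% with SMARCB1 and 8.79% with GFP (exact permutation p = 0.0286, adjusted 0.229).

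The difference of those effects asks whether the NSD1 guide changes the response to SMARCB1. It equals the NSD1 guide effect in SMARCB1 cells minus that in GFP cells, so a fall in GFP cells alone raises it. A difference above 0 can be a larger rise or a smaller fall with SMARCB1, so its sign does not give the strength of the response. The difference was above 0 for ETNK2, a phospholipid synthesis kinase (1.10 ± 0.08, edgeR adjusted p = 2.43e-06), the radial spoke gene RSPH4A (1.61 ± 0.17), and the glucose transporter SLC2A3 (0.81 ± 0.08). It was above 0 for the matrix genes SPARC (0.70 ± 0.07) and THBS1 (0.68 ± 0.05) too. It was below 0 for the homeobox gene DMBX1 (-1.84 ± 0.12, edgeR adjusted p = 1.93e-07), EPB41L1 (-0.69 ± 0.06), E2F2 (-0.54 ± 0.07) and IFITM1 (-0.44 ± 0.05). For E2F2, which SMARCB1 lowered with the control guide, this is a deeper fall. In all, 546 genes had a difference above 0 and 134 below 0, 84 and 7 of them by at least 2-fold. With libraries of title series 1 alone the edgeR count was 516, and with series 2 alone 2679; the labels do not say what the series are. The count was 1153 without SMARCB1 sgN 1_R2 and 445 without GFP sgC 1_R2.

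Calls of lists with a difference above 0 held with an estimated correlation in 8 cases. Higher and lower here mean a difference above or below 0. For genes that SMARCB1 lowered, such as CD74 and TAP1, higher means a smaller fall. Among antigen presentation genes, 4 of 15 were higher (6 higher and 1 lower adjusted over the list alone), with CD74 at 0.49 ± 0.06 and TAP1 at 0.43 ± 0.06 (adjusted p = 0.00665 with an estimated correlation). Among HOX genes, 8 of 34 were higher (17 adjusted over the list alone), with HOXB9 at 0.41 ± 0.06 and HOXC10 at 0.34 ± 0.05 (0.013). Among p53 targets, 10 of 23 were higher (14 over the list alone), with TP53I3 at 0.39 ± 0.07 and SESN1 at 0.27 ± 0.04 (0.0433). Among extracellular matrix genes, 5 of 25 were higher (9 higher and 1 lower over the list alone), with COL5A2 at 0.46 ± 0.06 (0.013). Contractile genes had 5 of 15 higher (6 over the list alone), with CALD1 at 0.69 ± 0.14 (0.013). Inflammatory NF-kB targets had 3 of 13 higher (6 over the list alone), with IL6 at 0.74 ± 0.12 and RELB at 0.64 ± 0.11 (0.013). Cell-cycle inhibitors had 2 of 11 higher (3 over the list alone), with BTG2 at 0.55 ± 0.08 (0.013). Imprinted genes had 2 of 14 higher (4 over the list alone), with DLK1 at 1.27 ± 0.23 (0.0224). Within SMARCB1 sgN cells, series 2 was lower than series 1 for 15 of 23 p53 targets (2 higher) and 6 of 13 NF-kB targets (1 higher). Of 11 cell-cycle inhibitors 5 were lower and 3 higher, and of 25 matrix genes 1 was lower and 10 higher. The differences for these lists therefore pool unlike libraries. Blocking both title numbers, which do not pair, ended the estimated calls of p53 targets (adjusted p = 0.0858 with an estimated correlation), matrix genes (0.104) and imprinted genes (0.128). Calls made at the preset correlation alone were developmental transcription factors with 4 of 27 higher (adjusted p = 0.0664 with an estimated correlation). YAP targets had 3 of 16 higher (7 over the list alone; adjusted p = 0.0514 with an estimated correlation). Proliferation genes were lower in 3 of 45 (4 over the list alone; adjusted p = 0.0537 with an estimated correlation). Ribosome biogenesis genes were called lower with 0 of 27 (adjusted p = 0.41 with an estimated correlation). The other such calls were cholesterol synthesis genes with 1 of 21 lower (adjusted p = 0.373 with an estimated correlation) and immune cell markers with 1 of 4 lower (0.0842). Higher were MAPK feedback genes with 1 of 23 (adjusted p = 0.442 with an estimated correlation) and stress response genes with 2 of 21 (0.41).

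Genes chosen in some libraries as raised by SMARCB1 were measured in others. The R2 libraries with the control guide gave 1134 genes raised at least 2-fold, of which 1123 were measured elsewhere. Their median SMARCB1 effect was 1.95 in the R3 control guide libraries and 2.35 with the NSD1 guide. The median difference was 0.22 (interquartile range -0.08 to 0.62) with 31.2% of genes lower (p = 0.000373 by fry, a rotation test; camera p = 0.00448 with an estimated correlation). Without the fold minimum 5567 genes had a median difference of -0.00284 with 50.9% of genes lower (camera p = 0.633 with an estimated correlation). Choosing in R3 and measuring in R2 at least 2-fold gave 1083 genes and a median difference of 0.22 (camera p = 0.0104 with an estimated correlation).

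The NSD1 guide was compared with the control guide in GFP cells, which asks what NSD1 editing does without SMARCB1. The steepest falls were taken among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups. They included genes of multiciliated cells: CDC20B (-2.17 ± 0.19), FOXJ1, the regulator of motile cilia (-2.14 ± 0.14, edgeR adjusted p = 4.58e-08), the sperm flagellar gene ROPN1L (-1.69 ± 0.12), CCNO (-1.52 ± 0.11) and RSPH4A (-1.45 ± 0.09). The ubiquitin ligase gene NEURL1B (-1.56 ± 0.11) and the septin SEPT3 (-1.38 ± 0.07) fell beside them. Rises were smaller and included the sphingolipid transporter SPNS2 (0.90 ± 0.12), the peroxisomal oxidase ACOX2 (0.70 ± 0.07), the natriuretic peptide receptor NPR1 (0.63 ± 0.11) and CORO1A (0.62 ± 0.07). Every library of one group lay outside the range of the other for each of these genes. By edgeR 606 genes rose and 1382 fell of 17367, 14 and 245 of them at least 2-fold. With series 1 alone 1194 genes were called and with series 2 alone 1827, against 1857 and 1168 per series with all libraries in the fit, and 1294 were called without GFP sgC 1_R3. With the compared groups alone in the fit 4711 genes were called.

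Of 34 HOX genes 15 fell and 1 rose (21 and 1 adjusted over the list alone), with HOXC11 at -0.72 ± 0.05, HOXC10 at -0.63 ± 0.03 and HOXB9 at -0.47 ± 0.04. The camera call held (adjusted p = 0.00242 with an estimated correlation). It held too for developmental transcription factors, with 13 lower and 1 higher of 27 (14 and 1 over the list alone), among them DLX2 at -0.72 ± 0.08 and DLX1 at -0.70 ± 0.05 (0.0173). Among cell-cycle inhibitors 5 of 11 fell (5 over the list alone), with CDKN1C at -1.53 ± 0.18, CDKN2B at -0.94 ± 0.14 and CDKN2A at -0.85 ± 0.12 (0.0108). Among extracellular matrix genes 9 of 25 fell and 1 rose (12 and 1 over the list alone), with COL6A2 at -1.04 ± 0.08 and SPARC at -0.49 ± 0.05 (0.0173). Antigen presentation genes had 5 of 15 lower (6 over the list alone), with HLA-B at -1.75 ± 0.23 and the MHC class I activator NLRC5 at -0.82 ± 0.14 (0.0178). Interferon-stimulated genes had 7 lower and 1 higher of 17 (the same over the list alone), with OAS3 at -0.66 ± 0.07 and IFI6 at -0.61 ± 0.09 (0.0173). Kidney development genes had 3 of 7 lower, with WNT4 at -1.30 ± 0.16 and PAX2 at -0.70 ± 0.14 (0.0154). Imprinted genes had 4 of 14 lower, with PEG3 at -0.41 ± 0.08 and PLAGL1 at -0.31 ± 0.07 (0.0353), both counts unchanged over the list alone.

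Calls that the estimated correlation ended included cholesterol synthesis, where 6 of 21 genes rose (8 over the list alone), with HMGCS1 at 0.26 ± 0.06 and FDPS at 0.19 ± 0.03 (camera adjusted p = 2.78e-06; adjusted p = 0.212 with an estimated correlation). Of 23 p53 targets 6 fell (9 over the list alone; adjusted p = 0.368 with an estimated correlation). Of 16 YAP targets 2 fell (3 over the list alone; adjusted p = 0.361 with an estimated correlation). Of 27 ribosome biogenesis genes 1 rose (adjusted p = 0.791 with an estimated correlation). Of 4 immune cell markers 2 rose, with CSF1R at 0.66 ± 0.10 (adjusted p = 0.061 with an estimated correlation). By edgeR 0 of 12 PRC2, 0 of 18 PRC1 and 0 of 11 H3K36 enzyme genes passed, and 2 of 45 proliferation genes rose.

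The same guides were compared in SMARCB1 cells. Here SEPT3 (-1.41 ± 0.07, edgeR adjusted p = 3.78e-09), the myosin MYH14 (-1.15 ± 0.09), EFHD1 (-1.03 ± 0.06), NPTXR (-1.03 ± 0.10) and the axonal kinesin KIF1A (-0.98 ± 0.17) fell. IGFN1 (1.29 ± 0.24), the potassium channel KCNJ16 (1.01 ± 0.23), CLSTN2 (0.96 ± 0.15), LRRN3 (0.77 ± 0.12) and the complement component C3 (0.77 ± 0.09) rose, again without overlap between the groups. Of 13 inflammatory NF-kB targets 6 rose and none fell (6 over the list alone), with IL6 at 0.63 ± 0.08, TRAF1 at 0.60 ± 0.12 and NFKBIA at 0.30 ± 0.04. This call held (adjusted p = 0.0315 with an estimated correlation). Within SMARCB1 sgN cells, series 2 was lower than series 1 for 6 of these 13 genes and higher for 1, so the effect pools unlike libraries. CDKN1C (-1.23 ± 0.15), CDKN2A (-0.84 ± 0.11), NLRC5 (-1.35 ± 0.14) and IFITM1 (-0.63 ± 0.04) fell as well, while CD74 rose (0.41 ± 0.04).

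Other lists were called in SMARCB1 cells at the preset correlation alone. Of 23 p53 targets 6 rose (9 over the list alone), with TP53I3 at 0.24 ± 0.05 (adjusted p = 0.314 with an estimated correlation). Within SMARCB1 sgN cells, series 2 was lower than series 1 for 15 of these 23 genes and higher for 2, so this effect pools unlike libraries. The same holds for stress response genes (14 lower and 3 higher of 21) and ribosome biogenesis genes (22 lower and 0 higher of 27). Of 15 contractile genes 5 rose (5 over the list alone), with CALD1 at 0.54 ± 0.11 and TAGLN at 0.35 ± 0.05 (adjusted p = 0.169 with an estimated correlation). Of 45 proliferation genes 4 fell (5 over the list alone), with E2F2 at -0.34 ± 0.05 (adjusted p = 0.156 with an estimated correlation). HOX genes gave 4 up and 7 down of 34 (5 and 7 over the list alone), with HOXB13 at -0.64 ± 0.08 (adjusted p = 0.314 with an estimated correlation). Interferon-stimulated genes gave 1 up and 3 down of 17 (adjusted p = 0.169 with an estimated correlation). YAP targets gave 1 and 1 of 16 (adjusted p = 0.368 with an estimated correlation), stress response genes 3 and 1 of 21 (0.621), and ribosome biogenesis genes 0 and 0 of 27 (0.737). By edgeR 637 genes rose and 611 fell of 17367, 25 and 79 of them at least 2-fold, and scaling by library totals alone gave 429 and 722. Series 1 alone called 580 genes and series 2 alone 5233, against 1222 and 3821 per series with all libraries in the fit, and 2783 were called without SMARCB1 sgN 1_R2. The compared groups alone gave 362. With the GFP comparison 350 falls were shared (48.6 for independent lists) and 87 rises (22.2).

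GSK126 was compared with DMSO in control hairpin cells, to see what EZH2 inhibition turns on. The YAP target ANKRD1 (6.49 ± 1.10), the cell-cycle inhibitor CDKN2B (4.36 ± 0.65, edgeR adjusted p = 0.00046), PPM1L (3.52 ± 0.62), the imprinted gene MEST (2.87 ± 0.57), the scavenger receptor COLEC12 (2.85 ± 0.51) and the laminin LAMB1 (2.82 ± 0.48) rose. They are among the steepest rises of genes with a mean of at least 5 CPM in GSK126 and no overlap with the DMSO libraries. The falls were shallow: CDC42EP4 (-0.50 ± 0.11), FBXO27 (-0.33 ± 0.10), DOK4 (-0.31 ± 0.08) and SPG7 (-0.19 ± 0.05). By edgeR 629 genes rose and 44 fell of 15454, 369 and 1 of them at least 2-fold, and blocking same-numbered pairs gave 2134 and 986. Leaving out shCTRL GSK126 6 gave 326 genes, shCTRL GSK126 7 353 and shCTRL DMSO 3 440. Library numbers fall into 4 runs in which the list of groups restarts, which the labels do not call batches. Within runs 1 to 4, edgeR called 0 (1 against 1), 0, 75 and 1427 genes (2 against 2 each), and runs 1 to 3 together gave 28 genes, or 1192 with pairs blocked. The genes that rose in the pooled test had median effects of 0.41, 0.70, 0.93 and 1.82 in the 4 runs. They were chosen in these same libraries, so medians above 0 follow from the choice. Genes raised by SMARCB1, chosen in the guide RNA experiment, had medians of 0.26, 0.45, 0.56 and 0.85.

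The lists called with GSK126 in control hairpin cells were all called at the preset correlation alone. Of 24 extracellular matrix genes 7 rose (12 rose and 1 fell adjusted over the list alone), with COL4A2 from 0.0222 to 0.543 CPM and COL8A1 from 0.0279 to 0.621 CPM (camera adjusted p = 1.43e-06; adjusted p = 0.104 with an estimated correlation). With pairs blocked 14 rose and 3 fell. Of 14 antigen presentation genes 3 rose (5 over the list alone), with ERAP2 at 1.99 ± 0.38 and NLRC5 at 1.91 ± 0.38 (adjusted p = 0.104 with an estimated correlation), and with pairs blocked 6 rose. Of 9 neuronal genes 4 rose (4 over the list alone; 5 with pairs blocked), with PROM1 at 4.05 ± 0.82 and MAP2 from 0.088 to 0.733 CPM (adjusted p = 0.355 with an estimated correlation). Of 11 cell-cycle inhibitors CDKN2B and CDKN2A (2.13 ± 0.40) rose (2 up and 1 down over the list alone; 5 and 1 with pairs blocked; adjusted p = 0.355 with an estimated correlation). Contractile genes had 4 of 14 higher, with CALD1 at 3.51 ± 0.80 and ACTA2 at 1.79 ± 0.40 (camera adjusted p = 0.0448; adjusted p = 0.355 with an estimated correlation). With pairs blocked 6 rose and the camera call was lost (adjusted p = 0.19). Kidney development genes had 2 of 11 higher (3 over the list alone), with PODXL at 1.97 ± 0.44 (adjusted p = 0.355 with an estimated correlation). Of 23 p53 targets 1 rose (6 with pairs blocked), FAS at 1.69 ± 0.39 (adjusted p = 0.435 with an estimated correlation).

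Smaller counts stood behind the remaining calls in these cells. YAP targets had 2 of 16 higher (3 over the list alone), MAPK feedback genes 1 of 24 and imprinted genes 1 of 14 (3 over the list alone), each with an adjusted p = 0.355 with an estimated correlation. PRC2 subunits were called lower, although the 1 of 12 that passed, JARID2, rose (0.41 ± 0.07; adjusted p = 0.355 with an estimated correlation). Cholesterol synthesis genes had 2 of 21 higher, with MSMO1 at 0.57 ± 0.12 (adjusted p = 0.502 with an estimated correlation). Epithelial markers had 1 of 7 higher, KRT19 at 2.76 ± 0.73 (adjusted p = 0.372 with an estimated correlation). Proliferation genes were called lower with 0 of 44 passing alone (mean -0.19; adjusted p = 0.372 with an estimated correlation). SWI/SNF subunits (0 of 25; adjusted p = 0.355 with an estimated correlation) and ribosome biogenesis genes (0 of 27; 0.769) were called lower, and TGF-beta response genes (0 of 15; 0.355) and NF-kB targets (0 of 12; 0.415) higher. No HOX gene of 34 passed and 1 of 27 developmental transcription factors did.

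GSK126 was compared with DMSO in NSD1 hairpin cells. OAF (1.15 ± 0.18, edgeR adjusted p = 0.00246), the actin-bundling LIM protein gene CSRP2 (0.93 ± 0.19), AFAP1 (0.93 ± 0.19), the surface glycoprotein gene THY1 (0.88 ± 0.12, edgeR adjusted p = 0.00106), and the ephrin EFNB1 (0.81 ± 0.18) rose. CDC42EP4 (-0.56 ± 0.12) and PEX13 (-0.22 ± 0.05) fell. CDKN2B was at 2.36 ± 0.66 (edgeR adjusted p = 0.112) and ANKRD1 at 3.05 ± 0.94 (0.155), so neither passed. Of 24 matrix genes 1 rose (3 over the list alone; 5 with pairs blocked), the matrix protein gene POSTN, from 0.0892 to 1.98 CPM (camera adjusted p = 0.00973; adjusted p = 0.542 with an estimated correlation). Of 14 antigen presentation genes 1 rose (1 over the list alone; 4 with pairs blocked), NLRC5 from 0.0613 to 0.254 CPM (adjusted p = 0.542 with an estimated correlation). Of 14 contractile genes 0 passed (1 over the list alone; adjusted p = 0.542 with an estimated correlation). With pairs blocked 2 of them rose and the camera call was lost (adjusted p = 0.0672). With pairs blocked, camera at the preset correlation also called cell-cycle inhibitors higher, with 2 of 11 up (adjusted p = 0.349 with an estimated correlation). So it did MAPK feedback genes with 1 of 24 up (adjusted p = 0.607 with an estimated correlation), TGF-beta response genes with 1 of 15 up (0.468) and hypoxia genes with 0 of 18 (0.679). It then called proliferation genes with 0 of 44 (adjusted p = 0.679 with an estimated correlation), ribosome biogenesis genes with 0 of 27 (0.607) and PRC2 subunits with 1 up and 1 down of 12 (0.463) lower.

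By edgeR 102 genes rose and 6 fell of 15454 in NSD1 hairpin cells, 29 and 0 of them at least 2-fold, and 691 and 94 with pairs blocked. Within runs 1 to 3, edgeR called 0, 1 and 303 genes (2 against 2, 1 against 2 and 2 against 2), no run 4 comparison exists, and 39 genes were called without shNSD1 GSK126 replicate 6. The compared groups alone gave 12 genes and DESeq2 235. The hairpin backgrounds shared 80 rises (4.15 for independent lists) and 3 falls (0.0171). Libraries of both hairpins share runs, so these lists need not be independent either.

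**Figure D2:**
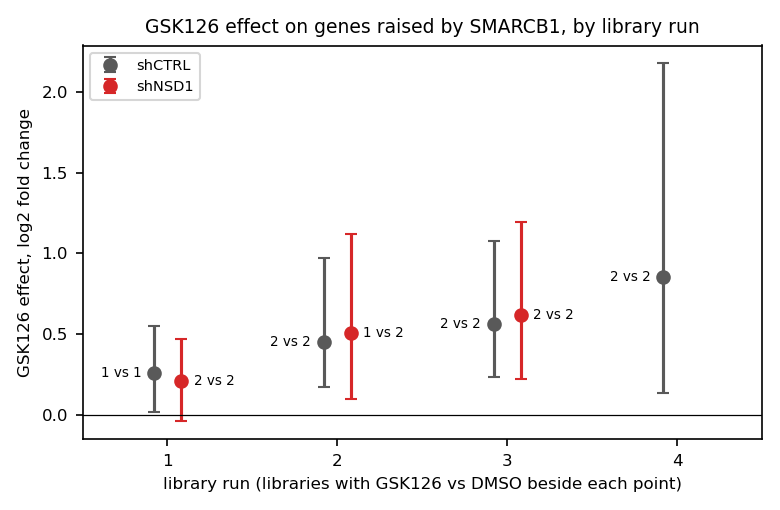
Median log2 GSK126 effect in each library run, by hairpin, over genes raised by SMARCB1 in the guide RNA experiment; bars give the interquartile range over genes and the text the libraries compared. Medians ran from 0.26 to 0.85 in control hairpin cells (runs 1 to 4) and from 0.21 to 0.62 in NSD1 hairpin cells (runs 1 to 3).

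The difference of the GSK126 effects asks whether the NSD1 hairpin changes the response to EZH2 inhibition. The hairpin lowered NSD1 mRNA only in part (means of 138 against 198.2 CPM in DMSO), so this cannot show whether NSD1 is needed. In simulated data this test recovered 28.8 to 29.9% of 1.5-fold changes, so smaller differences can be missed. In the real libraries no gene passed by edgeR, DESeq2 or limma-voom (0 each), and 327 had an unadjusted p under 0.05 by edgeR. Small p values belonged to SLC2A4RG (0.33 ± 0.11), JDP2 (0.54 ± 0.18) and the TGF-beta co-receptor TGFBR3 (-0.79 ± 0.25), each at an adjusted p of 1. With pairs or runs blocked the count stayed at 0. Camera at the preset correlation called proliferation genes higher (mean 0.22; 0 of 44 passed alone; adjusted p = 0.716 with an estimated correlation) and p53 targets lower (mean -0.28; 0 of 23; 0.716). It called ribosome biogenesis genes higher (mean 0.14; 0 of 27; adjusted p = 0.724 with an estimated correlation), SWI/SNF subunits higher (0 of 25; 0.716) and matrix genes lower (mean -0.69; 0 of 24; 0.716). With pairs blocked the matrix (adjusted p = 0.0687), SWI/SNF (0.147) and ribosome biogenesis (0.976) calls were lost, and cholesterol synthesis, HOX, hypoxia, MAPK feedback and YAP lists were called at the preset correlation with 0 members passing (smallest adjusted p = 0.689 with an estimated correlation). A set chosen in odd-numbered control libraries could not be made without a pair block, since 0 genes passed there. With pairs blocked it had 140 genes, 138 of them measured elsewhere, with a median effect of 1.57 in the even-numbered control libraries and 1.06 in NSD1 hairpin cells. The median difference was -0.42 (interquartile range -0.83 to -0.09; 80.4% of genes lower; fry p = 0.331; camera p = 0.217 with an estimated correlation), and -0.07 in runs 1 to 3 (fry p = 0.924).

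The NSD1 hairpin was compared with the control hairpin in DMSO. ETNK2 (-2.52 ± 0.15, edgeR adjusted p = 9.4e-12), the Rac exchange factor PREX1 (-2.66 ± 0.24), the vitamin A enzyme CYP27C1 (-2.60 ± 0.27), the LIM protein gene FHL1 (-2.42 ± 0.38), and RASSF2 (-2.39 ± 0.16) fell. So did the class I genes HLA-B (-2.21 ± 0.35) and HLA-C (-2.06 ± 0.23) and the laminin LAMC3 (-2.03 ± 0.14). The dynein light chain DYNLRB1 (0.99 ± 0.09), the galectin LGALS3 (0.97 ± 0.16), NUDT19 (0.95 ± 0.07, edgeR adjusted p = 3.14e-10) and the glutamine synthetase gene GLUL (0.76 ± 0.11) rose. The libraries of the groups did not overlap for these genes. Of 34 HOX genes 4 fell (5 fell and 1 rose over the list alone), with HOXB9 at -1.35 ± 0.36 and HOXC10 at -0.42 ± 0.09 (camera adjusted p = 0.0162; adjusted p = 0.989 with an estimated correlation). With runs blocked 9 fell and 1 rose. Of 14 antigen presentation genes 4 fell and 1 rose (the same over the list alone), with NLRC5 from 0.329 to 0.0613 CPM (camera adjusted p = 0.0162; adjusted p = 0.698 with an estimated correlation). The list was called lower with a mean of -0.43 and a median of 0.01. Members of lists that were not called included SPARC (-1.70 ± 0.23), COL6A2 (-1.04 ± 0.27), CDKN2A (-1.47 ± 0.39), OAS3 (-1.47 ± 0.27), DLX1 (-0.67 ± 0.20) and PEG3 (-0.45 ± 0.12), which fell, and SS18 (0.48 ± 0.06), which rose. By edgeR 408 genes rose and 479 fell of 15454, 45 and 258 of them at least 2-fold. With runs blocked the counts were 1529 and 1389, and camera at the preset correlation then also called ribosome biogenesis genes (8 of 27 down; adjusted p = 0.844 with an estimated correlation), proliferation genes (6 of 44 down; 0.88) and hypoxia genes (4 of 18 up; 0.844). Within runs 1 to 4 edgeR called 35 (2 against 1), 678, 575 and 105 genes (2 against 2 each), with the spread taken over all groups of the run.

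In GSK126 the NSD1 hairpin lowered the ephrin receptor EPHB2 (-3.57 ± 0.55), FHL1 (-2.88 ± 0.45), HLA-B (-2.78 ± 0.43), the splicing factor NOVA2 (-2.73 ± 0.54), PROSER2 (-2.71 ± 0.38) and SLFN5 (-2.64 ± 0.43). It raised DYNLRB1 (1.20 ± 0.10, edgeR adjusted p = 4.57e-09), SNX15 (1.06 ± 0.10), NUDT19 (0.99 ± 0.07) and CP (0.96 ± 0.21), without overlap between the groups. Of 24 matrix genes 4 fell (4 over the list alone), with FBLN5 down to 0.0655 CPM and SPARC at -1.97 ± 0.27 (camera adjusted p = 0.0192; adjusted p = 0.612 with an estimated correlation). Of 14 antigen presentation genes 4 fell and 1 rose (the same over the list alone), with NLRC5 at -2.26 ± 0.43 and HLA-C at -2.18 ± 0.27 (adjusted p = 0.612 with an estimated correlation). Of 19 interferon-stimulated genes 2 fell, with OAS3 at -1.38 ± 0.32 (adjusted p = 0.612 with an estimated correlation; call lost with runs blocked, adjusted p = 0.166). Of 23 p53 targets 3 fell, with FAS at -1.41 ± 0.44 (adjusted p = 0.745 with an estimated correlation). SWI/SNF subunits gave 3 up and 1 down of 25, with SS18 at 0.56 ± 0.07 (adjusted p = 0.612 with an estimated correlation). Proliferation genes were called higher with 0 of 44 passing alone (adjusted p = 0.843 with an estimated correlation; call lost with runs blocked, adjusted p = 0.195). With runs blocked, 8 of 18 hypoxia and glycolysis genes rose and camera called the list, as it did ribosome biogenesis genes with 3 of 27 down (both adjusted p = 0.825 with an estimated correlation). CDKN2B (-3.38 ± 0.71), CDKN2A (-2.21 ± 0.46) and the podocyte gene PODXL (-2.91 ± 0.53) were lower in lists without a call. All of them rose with GSK126 in control hairpin cells. Run 4 holds GSK126-treated shCTRL libraries and none of shNSD1, so the folds of this comparison are not told apart from that run. By edgeR 463 genes rose and 785 fell of 15454, 27 and 455 of them at least 2-fold, against 1421 and 1483 with runs blocked. Within runs 1 to 3 edgeR called 36, 98 and 820 genes (2 against 1, 1 against 2 and 2 against 2), where an arm of 1 library leaves the spread to the other groups. With the DMSO comparison 369 falls (24.3 for independent lists) and 211 rises (12.2) were shared. DMSO and GSK126 libraries of a hairpin share runs and correlate, so these lists need not be independent.

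**Figure D3:**
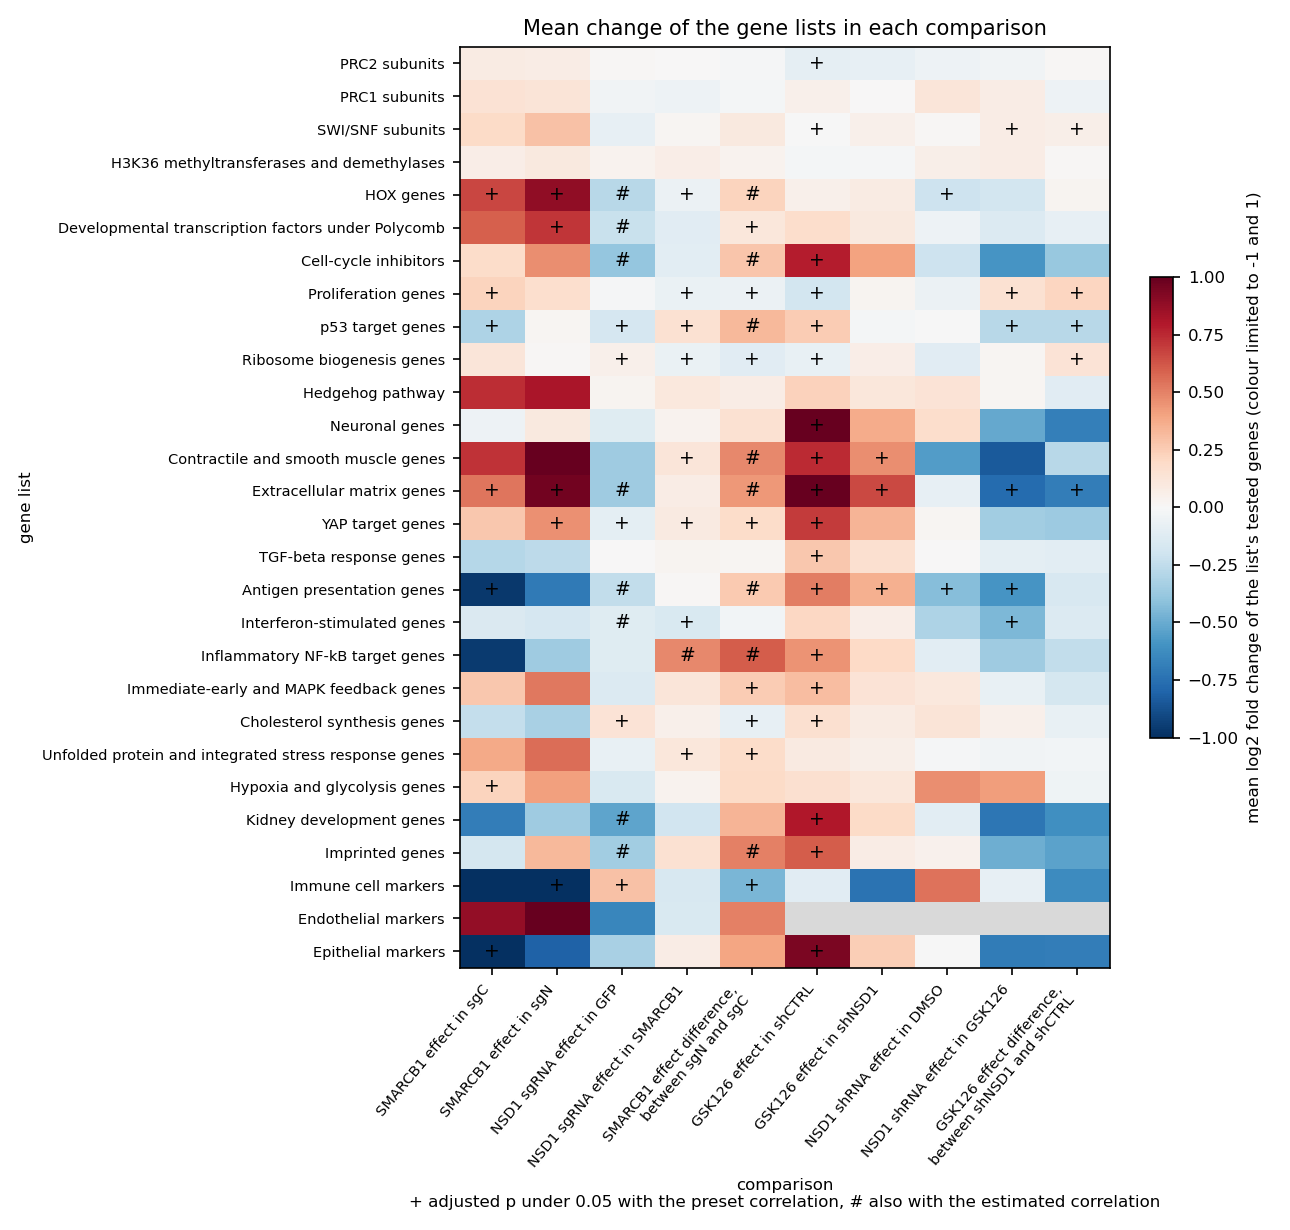
Mean log2 fold change of each fixed gene list (rows) in each comparison (columns); + marks a camera call at the preset correlation and # one that also held with an estimated correlation, and grey fields were not tested. HOX, matrix, antigen presentation and cell-cycle inhibitor lists carry # for the NSD1 guide in GFP cells and for the difference of the SMARCB1 effects, in which the same GFP libraries enter with reversed sign.

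Gene sets chosen in one experiment were carried to the other, which shares no library with it. Genes raised at least 2-fold by GSK126 in control hairpin cells (369, of which 285 were tested) were higher with SMARCB1, with a median of 1.56 with the control guide, where 207 rose and 57 fell (camera p = 0.000987 with an estimated correlation). With the NSD1 guide the median was 1.86, with 219 up and 44 down (0.000671). The NSD1 guide itself lowered that set in GFP cells, with a median of -0.41, 2 up and 93 down (camera p = 0.000368 with an estimated correlation). In SMARCB1 cells its median was -0.02, with 17 up and 33 down (camera p = 0.175 with an estimated correlation). The difference of SMARCB1 effects had a median of 0.39, with 38 higher and 0 lower (0.00126).

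Genes raised at least 2-fold by SMARCB1 (1157, of which 820 were tested) had a median GSK126 effect of 0.56 in control hairpin cells, with 231 up and 0 down (camera adjusted p = 0.000858 with an estimated correlation; 473 and 5 with pairs blocked). Without the fold minimum 4989 tested genes had a median of -0.00375 there (camera adjusted p = 0.793 with an estimated correlation). In NSD1 hairpin cells the median was 0.36, with 36 up and 0 down (adjusted p = 0.0066 with an estimated correlation; 175 and 1 with pairs blocked). The difference between hairpins for this set was -0.20 (camera adjusted p = 0.253 with an estimated correlation), and -0.00953 in runs 1 to 3, or -0.0253 there with pairs blocked; run 4 holds no GSK126-treated NSD1 hairpin library. The NSD1 hairpin gave the set a median of -0.17 in DMSO, with 17 up and 123 down (adjusted p = 0.0884 with an estimated correlation; with runs blocked 62 and 201, adjusted p = 0.0415). In GSK126 the median was -0.47, with 11 up and 193 down (adjusted p = 0.0273 with an estimated correlation). Genes lowered by SMARCB1 (1347 tested) had a median GSK126 effect of 0.09 in control hairpin cells, with 56 up and 3 down (camera p = 0.524 with an estimated correlation).

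**Figure D4:**
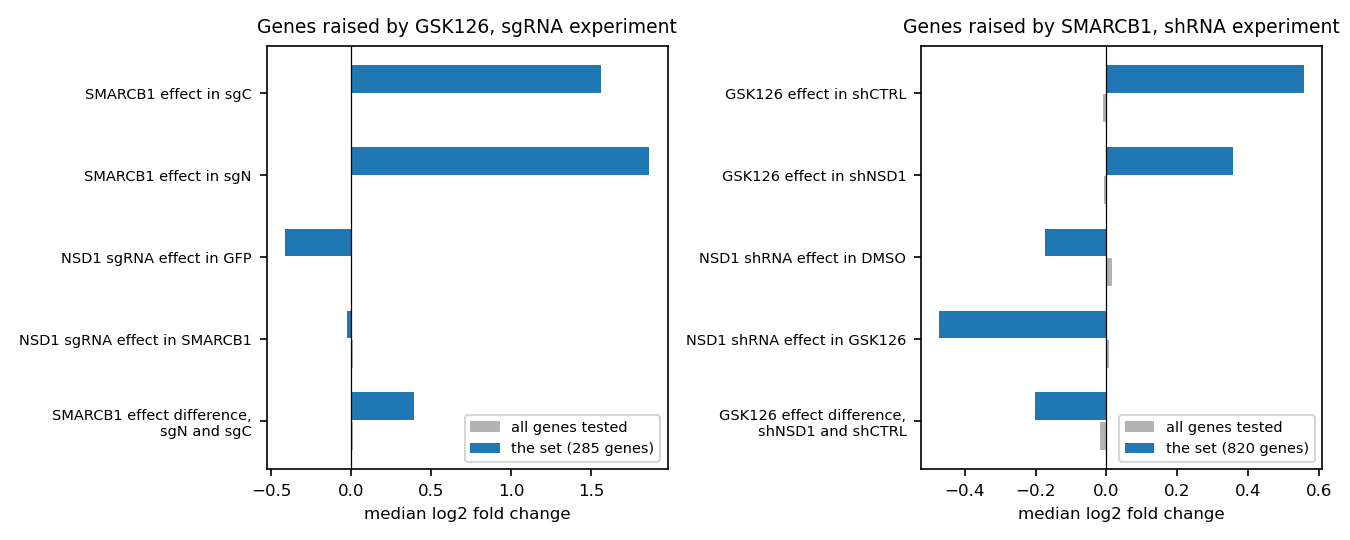
Median log2 fold change of the genes raised by GSK126 (left, 285 genes) and by SMARCB1 (right, 820 genes) in the comparisons of the other experiment (blue bars), beside the median of all genes tested (grey bars). The set raised by GSK126 lay above 0 with SMARCB1 (medians of 1.56 and 1.86) and below 0 with the NSD1 guide in GFP cells (median of -0.41).

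The falls with the NSD1 guide in GFP cells and with the NSD1 hairpin in DMSO overlapped. Both lowered 238 genes, among them ETNK2, ZCCHC24, RASSF2, RIMS4, EPHB3, SPARC and EFHD1, where independent lists would share 39.4 (Fisher's exact p = 1.18e-136). Both raised 35 genes (14.8; Fisher's exact p = 2.24e-06). Of falls of at least 2-fold 51 were shared (3.13 for independent lists). Between the SMARCB1 arm of one experiment and the GSK126 arm of the other, 151 falls (28.1) and 28 rises (19) were shared, while 33 genes that rose with the guide fell with the hairpin (29.6). Over all genes those arms had a Pearson r of 0.158 and a Spearman rho of 0.0173. Across 14071 genes, which are not independent replicates, the effects in GFP and DMSO had a Pearson r of 0.319 and a Spearman rho of 0.213. SMARCB1 and GSK126 in control cells both raised 370 genes, where independent lists would share 192.5 (Fisher's exact p = 4.29e-56). Both lowered 21 (14.7; Fisher's exact p = 0.0528), and over all genes the Pearson r was 0.185 and the Spearman rho 0.073.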

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

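The test of run 4 was chosen only after its result was seen, as were the fits with pairs blocked within a hairpin, those on runs 1 to 3 and those without the doubted pair of libraries; the other tests of this part were planned. A gap rule for groups of 4 to 10 libraries (Dixon's test at 95%) marked 8 of 60 single values and 37 of 496 combinations of named gene and group, where chance alone marks about 1 group in 20.

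GSK126 changed 673 genes in control hairpin cells and 108 in NSD1 hairpin cells, and the test of the difference between hairpins called none. Run 4 holds GSK126-treated control hairpin libraries and none of the NSD1 hairpin: with runs 1 to 3 alone the counts were 28 and 144 (control, NSD1 hairpin), which is what run 4 as the source of the imbalance would give. Taking 5 of the 7 treated control libraries in all 21 ways gave a median of 427 genes (60 to 1005). The median was 655 (487 to 1005) when both run 4 libraries were among them, 329 (204 to 427) with 1 of them and the count 60 with neither, so run 4 may account for the imbalance, and 5 libraries with both of run 4 kept a median near the full 673. A weaker response of NSD1 hairpin cells stays open. The genes raised by SMARCB1 were measured in runs 1 to 3 with pairs blocked. Their median difference between hairpins was -0.0253 (camera p = 0.764 with an estimated correlation).

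The NSD1 guide effect in SMARCB1 cells differed between title series 1 and 2 in 2057 genes (a difference between groups by its own test), against 2 genes in GFP cells. Leaving out SMARCB1 sgC 1_R3, the library with the lowest SMARCB1 level of its group, left 3218 genes, so that library was not the cause. The series differed within SMARCB1 sgN cells in 5356 genes, against 4 in SMARCB1 sgC cells, with ASNS (-1.36), TRIB3 (-1.53) and CHAC1 (-1.52) of the integrated stress response lower in series 2 and the imprinted RNA H19 higher (2.35). SMARCB1 mRNA in sgN cells was not lower in series 2 (3560 and 3663 CPM) than in series 1 (3262 and 3554 CPM), which speaks against weaker SMARCB1 induction there. For it speaks that genes raised by SMARCB1 had a median difference of -0.1195, under the -0.1 set beforehand (interquartile range -0.58 to 0.38), and that the series difference had a Pearson r of -0.114 with the SMARCB1 effect over all genes and -0.266 over the 5356, so this stays open, as does a difference between guides, cultures or handling, since the labels do not say what the series are.

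SMARCB1 in the GFP sgN library 2_R2 was 22.05 CPM, far from the other libraries of its group, or 0.593% of the mean of SMARCB1 cells. RNA or reads of SMARCB1-expressing cells may be the source but this stays open. For 26 other genes far lower without SMARCB1, that library had a pooled excess of 0.411% of their SMARCB1 level over its group. The other GFP libraries, each against its own group, had -0.0798 to 0.0901%. Not all these genes were near 0: LAMB1 and GPR126 had means of 7.52 and 1.66 CPM in the other GFP libraries, where the pool was at 9.5 to 12.8 CPM. Variation of these genes can therefore weigh on the excess. Over all other GFP libraries it was 0.227%, within the -0.278 to 0.241% of the others, and the 2 baselines were kept apart only after a result that mixed them was seen. Counts without this library and SMARCB1 sgC 1_R3 stayed near the full ones (1774 genes for the NSD1 guide in GFP cells, 1004 in SMARCB1 cells, and 558 for the difference). No biological explanation was tested.

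The difference between the SMARCB1 effects with the NSD1 and the control guide passed its own test in 680 genes, and in the genes chosen in other libraries as raised at least 2-fold by SMARCB1 its median was 0.2225, against -0.00284 without the fold minimum. The SMARCB1 level in SMARCB1 sgC 1_R3 was 3441 CPM, against 4077 to 4091 CPM in the other 3. The mitochondrial share of SMARCB1 sgC 2_R2 was 7.534%, against 7.77 to 7.80% in its group. NSD1 in shCTRL DMSO 3 was 146.8 CPM (200.2 to 219.5 in the others), and the 10 most counted genes took 4.508% of its counts (4.193 to 4.261%). The library shNSD1 DMSO 7 had 63.8 M counts (32.4 to 46.3 in the others) and a ribosomal protein share of 7.793% (6.044 to 6.8%). The share of replication-dependent histone genes in shNSD1 GSK126 2 was 0.0129% (0.00992 to 0.0103%). Among 61 named genes, a gap was found for 2 in GFP sgC, 4 in SMARCB1 sgC, 9 in GFP sgN (5 of them in 2_R2) and 10 in SMARCB1 sgN (9 of them in 1_R2). Among 63 named genes it was found for 3 in shCTRL DMSO, 2 in shCTRL GSK126, 5 in shNSD1 DMSO and 2 in shNSD1 GSK126.

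Other splits of the same libraries were counted. For SMARCB1 with the control guide 1 of 35 splits gave as many genes as the real 11270 (highest other 1), and with the NSD1 guide 1 of 35 (10872, highest other 1). For the NSD1 guide in GFP cells it was 1 of 35 (1988, highest other 1). No other split came near, but 1 of 35 is the smallest share that 4 against 4 can give. All splits take libraries as separate units, which the labels do not state. Chance is called excluded below only on that reading. For the NSD1 guide in SMARCB1 cells 3 of 35 splits gave as many as the real 1248, so chance is not excluded. The highest other, 2475, parts the SMARCB1 sgN libraries by title series, and the split that follows the title series gave 1740, while series 1 alone gave 580 and series 2 alone 5233 (1222 and 3821 with all libraries in the fit). For the difference of SMARCB1 effects 2 of 100 splits reached the real 680, with a highest other of 2143, several times the real count. These splits shuffled the guide labels within SMARCB1 and within GFP libraries, so they removed the guide effect itself too. They therefore cannot exclude chance for the difference alone. Whether a split follows title series or R number was not checked for this comparison. For GSK126 in control hairpin cells 1 of 100 splits reached 673 (highest other 237), as did 1 of the 64 splits that part every pair (highest other 237), which excludes chance. For GSK126 in NSD1 hairpin cells 1 of the 32 splits that part every pair reached 108 (highest other 0), the smallest share that 32 splits can give. Same-numbered libraries within a hairpin share a run, so these splits do not separate the number from the run. Of splits that ignore the pairs 6 of 100 reached 108, so over those chance is not excluded. Their highest other, 1365, sets 5 libraries of runs 1 and 2 against the rest. With runs blocked the real count was 637. For the NSD1 hairpin in DMSO 2 of 100 splits reached the real 887. The highest other, 1304, is above the real count and gathers 7 of the 8 libraries of runs 3 and 4. With runs blocked the real count was 2918. In GSK126 1 of 100 splits reached 1248 (highest other 412). Both shares are small, but these splits ignore the runs, and run 4 holds no GSK126-treated NSD1 hairpin library. They therefore cannot exclude chance apart from the runs. For the difference of GSK126 effects 100 of 100 splits reached the real 0 (highest other 38), and 64 of 100 reached the 327 genes at an unadjusted p under 0.05 (highest other 2832).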

How the results depend on the processing

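Pair blocks within a hairpin, fits on runs 1 to 3, set choices with a pair block and leaving out the doubted pair of libraries were chosen only after the data were seen; the others were planned. The counts for SMARCB1 stayed within 1.5 times under every alternative, and leaving out each library gave 10715 to 11626 with the control guide and 10352 to 11209 with the NSD1 guide. For the NSD1 guide in GFP cells, the compared groups alone gave 4711 genes and series 1 gave 1194, and leaving out each library gave 1294 (without GFP sgC 1_R3) to 2364. In SMARCB1 cells, the compared groups alone gave 362, series 1 580 and series 2 5233, and leaving out each library 833 (without SMARCB1 sgN 2_R3) to 2783 (without SMARCB1 sgN 1_R2). For the difference, DESeq2 gave 1074 and series 2 2679, and leaving out each library 445 (without GFP sgC 1_R2) to 1153 (without SMARCB1 sgN 1_R2). Same-numbered libraries of the guide RNA experiment did not pair (-0.0515 to 0.0782, 0 of 8 over 0.1), and blocking both title numbers gave 11138, 10796 and 516 genes for the SMARCB1 effects and their difference. That block added camera calls at the preset correlation for developmental transcription factors and interferon-stimulated genes with the control guide (both adjusted p = 0.0256), and for cholesterol synthesis (0.0364) and imprinted genes (0.0292) with the NSD1 guide. For the difference it ended that of immune cell markers (0.0576), and with an estimated correlation the calls of p53 targets (0.0858), matrix genes (0.104) and imprinted genes (0.128). In the hairpin experiment, title-number blocks gave 1216 and 163 genes for GSK126 (shCTRL, shNSD1) and 1454 and 1924 for the NSD1 hairpin (DMSO, GSK126). Run blocks gave 1962, 637, 2918 and 2904 in the same order, pair blocks within a hairpin 3120 and 785 for GSK126. Runs 1 to 3 alone gave 28 for GSK126 in shCTRL, with run blocks 420, 582, 1980 and 2155, and with pair blocks 1192 and 1153. For GSK126 in shNSD1, DESeq2 gave 235 and the compared groups alone 12. Leaving out each library gave 326 (without shCTRL GSK126 6) to 790, 39 (without shNSD1 GSK126 6) to 157, 638 to 949 and 861 to 1523 in that order. GSK126 in shCTRL also gave 353 without shCTRL GSK126 7 and 440 without shCTRL DMSO 3. GSK126 in shNSD1 gave 40, 54 and 71 without shNSD1 GSK126 5, 3 and 2, and 62, 67, 66, 66 and 58 without shNSD1 DMSO 3, 4, 5, 6 and 8. For the difference of GSK126 effects every alternative and every left-out library gave 0 (0 to 0). The cause of these moves was not tested, apart from thinning the GSK126-treated shCTRL libraries. The held-out GSK126 set, empty as planned, had 140 genes with a pair block, 397 without fold minimum and 7 when chosen in even numbers. An estimated correlation changes only the p of a set test and leaves the median as in the main fit. Without fold minimum the held-out difference for SMARCB1 was -0.00284. The GSK126-raised set with the NSD1 guide in SMARCB1 cells had a median of 0.00681 without fold minimum, against -0.0226 in the main fit. The SMARCB1-raised set without fold minimum had medians of -0.00375 (GSK126, shCTRL), 0.00735 (NSD1 hairpin, GSK126) and 0.0211 (difference). With the fold minimum its difference was -0.2005 in the main fit and -0.00953 in runs 1 to 3. There it was -0.0253 with pairs and -0.0256 with runs blocked. The SMARCB1-lowered set, whose medians lie near 0, gave -0.00611 without fold minimum and 0.0865 in the main fit for GSK126 in shCTRL. In shNSD1 it gave -0.056 without fold minimum, 0.0686 with pairs and 0.0299 with runs blocked, and 0.0748, 0.0734 and 0.0555 in runs 1 to 3 (no block, pairs, runs). For the NSD1 hairpin in DMSO it gave 0.0536 without fold minimum and 0.1056 with runs blocked, and in GSK126 0.038 with runs blocked and 0.0597 and 0.0435 in runs 1 to 3 (no block, runs). Its difference was -0.1787 in the main fit, -0.0244 with pairs and -0.0641 with runs blocked. In runs 1 to 3 it was -0.0096, -0.0189 and -0.0267 (no block, pairs, runs). Shared rises between the NSD1 guide and hairpin fell to 0 with a 2-fold minimum in both pairs of arms. Of 84 list calls at the preset correlation 17 held with an estimated one, and 87 were made with title-number blocks. Under every alternative, 125 of 129 called named genes kept their call for SMARCB1 with the control guide, and with the NSD1 guide 126 did (1 did not). The counts were 53 of 79 and 32 of 79 for the NSD1 guide (GFP, SMARCB1 cells), 35 of 61 for the difference, 4 of 41 and 4 of 12 for GSK126, and 31 of 43 and 32 of 52 for the NSD1 hairpin; none changed sign. Under 3 measured members left 2 of 30 lists untested in the guide RNA experiment and 3 in the hairpin experiment.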

Other observations

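The list of motile cilia genes was written, and the test of its members not seen first was chosen, only after the largest falls in GFP cells were seen; its test in the hairpin experiment was written before its result was.

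With the NSD1 guide in GFP cells, genes of motile cilia were lower as a group. Of 67 measured members 37 fell and 0 rose (43 and 0 adjusted over the list alone). Of the 60 that were not among the largest falls 30 fell (36 over the list alone), with a mean log2 change of -0.56 (camera p = 0.00013 with an estimated correlation). In SMARCB1 cells 3 rose and 1 fell (camera p = 0.755 with an estimated correlation). The difference of the SMARCB1 effects, which falls in GFP cells raise by construction, was higher for 26 of 67 (34 over the list alone, camera p = 7.7e-05 with an estimated correlation). Of the 60 members not seen first 19 were higher (camera p = 0.000371 with an estimated correlation). SMARCB1 itself lowered 55 and raised 4 of the 67 with the control guide (camera p = 0.00955 with an estimated correlation), and lowered 44 and raised 6 with the NSD1 guide (camera p = 0.16 with an estimated correlation). The median SMARCB1 effect with the control guide was -0.89, and that of the NSD1 guide -0.32 in GFP cells and 0.02 in SMARCB1 cells. Why the guide lowered them in GFP cells alone was not found. The NSD1 hairpin in DMSO moved the list by a mean of -0.0165 (2 up and 2 down of 64; camera p = 0.869 with an estimated correlation).

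Within SMARCB1 sgN cells, series 2 was lower than series 1 for 14 of 21 unfolded protein and stress response genes (adjusted p = 0.0208 with an estimated correlation), and 14 of 23 MAPK feedback genes (0.0165). So it was for 22 of 27 ribosome biogenesis genes (0.0276), 15 of 23 p53 targets (0.0208) and 7 of 17 hypoxia genes (0.0431). It was higher for 12 of 21 cholesterol synthesis genes (adjusted p = 0.0524 with an estimated correlation) and 10 of 25 matrix genes (0.138). In series 1 and series 2 the histone share was 0.0104 and 0.00967%, and 0.0052 and 0.00522%. The ribosomal protein share was 6.73 and 6.37%, and 6.02 and 5.95%, the mitochondrial share 7.46 and 8.04%, and 8.29 and 8.16%. NSD1 was at 115 and 130.3 CPM, and 154.1 and 152.9 CPM, and no test was made on these 2 libraries each. Single genes included GDF15 at -1.65, STC2 at -1.77, HMOX1 at -1.23, ETV5 at -1.25, DUSP6 at -0.73, COL3A1 at 1.05 and FMO1 at 1.10. Across genes, the NSD1 guide effects in series 1 and series 2 had a Pearson r of 0.117 in SMARCB1 cells and 0.32 in GFP cells; genes are not independent replicates.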
